A study of Mus musculus with 21 samples.

How the data were processed

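The series holds 8 iCLIP libraries of md MEPA cells, 4 with an antibody that recognises both RBM10 isoforms and 4 with rabbit IgG, and 13 RNA-seq libraries of polyadenylated RNA. The latter are 4 Rbm10 KO and 3 WT md MEPA samples and 3 samples each of an Rbm10 gene trap ES line and its parental line. Groups and replicate numbers were taken from the sample titles, and the exon of each md deletion from the design text. Nothing in the labels says that the WT md samples or the ES samples of a line came from separate cultures, so their p-values measure the spread between these samples, which may be technical. The md clones are separate lines.

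For iCLIP the authors deposited crosslink counts per nucleotide position and strand for each library. Per the design text the reads were mapped to mm9 and the crosslinked nucleotide was deduced from them. For RNA-seq the authors deposited TPM per transcript in 1 table per cell type. The builds mm9 and mm10 are both named in the submitters' processing notes without a role. The aligner, the quantifier, the annotation release, the strandedness and the handling of duplicate reads are not given in the sources used here. Each TPM column sums to the same total, so RNA-seq depth is unknown and no interval for counting error can be given. Of 100249 listed transcripts 84877 (84.7%) were joined by identifier to the GENCODE vM1 annotation of mm9, and of those with a mean of at least 1 TPM 91.4% in md and 91.3% in ES cells. All coordinates are those of mm9. Reads of overlapping genes, antisense pairs and near-identical copies such as Eif2s3x and Eif2s3y cannot be told apart with certainty in such values.

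Gene TPM was the sum over a gene's joined transcripts. Genes with at least 1 TPM in at least 3 libraries of a comparison were tested on log2(TPM + 1) with limma 3.58.1 (eBayes with trend, R 4.3.3, 2-sided), so a fold change is on the log2(TPM + 1) scale and understates that of low genes. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Splice events were built from the annotation's exon chains. PSI is the share of TPM of transcripts that include an exon or site among those that include or skip it. Events with at least 1 TPM in every library and a mean PSI between 5 and 95% were tested with limma on PSI, each event type adjusted on its own. A call also needed a difference of at least 10 points. Transcript shares of gene TPM were tested likewise. PSI from transcript TPM depends on how the quantifier divided reads among transcripts. The clone contrast and the difference between cell types were limma contrasts with all groups concerned in 1 fit.

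Crosslinks were summed in windows of 5000 nt per strand and over gene bodies, and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr). DESeq2 1.42.0 was an alternative. Crosslinks were counted as deposited, and whether molecular barcodes had been collapsed is not stated, so a position with many crosslinks can hold copies of the same molecule. Shares of region classes, snRNA families and chromosomes were compared by exact permutation tests over the 70 splits of 4 against 4, with a smallest 2-sided p of 0.0286, and by exact sign flips of the 4 pairs, with a smallest p of 0.125. Each intronic base within 100 nt of an annotated splice site was counted as near it. Crosslinked positions beside exons were compared with those of exons from 10 groups of like expression by 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0 were used.

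The 27 gene lists were tested with camera (preset correlation 0.01, and with an estimated correlation). They are RBM10 and related RNA-binding proteins, splicing factors, reported RBM10 splicing targets, pharyngeal arch patterning, palate development, bone and cartilage, extracellular matrix, pluripotency, germ layers and exit from pluripotency, the 2-cell-like state, the Notch pathway, p53 targets, apoptosis, the cell cycle, the interferon response, stress and immediate early genes, genes beside Rbm10, sex chromosome genes, imprinted genes, histone genes, mitochondrially encoded genes, and markers of epithelial, endothelial, leukocyte, skeletal muscle, neural and fibroblast feeder cells. Some genes stand in more than 1 list.

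Named genes followed a rule. It took Rbm10, Rbm5 and Rbm6, the 10 highest and 10 lowest called genes per cell type with a mean of at least 5 TPM in the higher group, groups that do not overlap and no predicted, RIKEN, microRNA or pseudogene symbol, and up to 4 members with the lowest p of lists that passed or had at least 3 called members. It also took up to 15 called cassette exons, the 10 windows with the lowest p among those higher in RBM10, the 5 windows with the highest counts, and 5 genes per direction for the clone contrast and the cell type difference. Members of other lists and of the other splice events, the iCLIP genes, and those the text says so of were named after their values were seen. Some genes the rule takes are not reported here.

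The tests, lists, naming rule and most alternatives were chosen before the data were examined. The iCLIP region classes, splice-site regions, base composition, snRNA families, iCLIP genes, crosslinks beside exons, exons shared by both cell types, the test of neighbouring genes and the Y-linked genes were added later. The alternatives were other pseudocounts, filters, scalings, window sizes and tools, sample weights, a replicate block, the logit scale and leaving out each library.

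Each iCLIP replicate had its own IgG control per the design text, so the replicate numbers pair the libraries. The deviations of same-numbered libraries from their group means were nearly uncorrelated (-0.0330, 0.0037, -0.0256 and -0.0002).

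The fits were checked on simulated data with 200 genes or windows changed. At 2-fold and 4-fold, limma recovered 57% and 86% of md genes and 70% and 96% of ES genes. At 2-fold and 4-fold, edgeR recovered 10% and 65% of windows and 43% and 84% of iCLIP genes. Changes of 20 and 40 points, set in 200 exons of intermediate mean PSI, were recovered for 71% and 96% of md and 67% and 90% of ES cassette exons. Recovery may be lower for other exons, and where fewer exons, genes or windows change than were simulated.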

Results

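RBM10, an X-linked RNA-binding protein that regulates alternative splicing, was examined in 2 ways. Its RNA contacts were mapped by iCLIP, in which UV light links protein to RNA in living cells and the crosslinked nucleotide is read from the sequenced fragment. The cells were md MEPA cells, a line from the mandibular part of the mouse embryonic pharyngeal arch. There were 4 RBM10 libraries, and each replicate had its own control precipitation with rabbit IgG. The RBM10 libraries held 1114788, 2847066, 2845634 and 774816 crosslinks, and the IgG libraries 965090, 2214515, 103017 and 157986. RNA-seq of polyadenylated RNA covered 4 Rbm10 knockout (KO) clones and 3 wild-type (WT) samples of md MEPA cells. Clones KO1 and KO2 carry a CRISPR deletion in exon 3, and clones KO3 and KO4 in exon 9. It also covered 3 samples of a male gene trap ES cell line and 3 of its parental line, E14Tg2a.4. The RNA-seq values were TPM, so the read depth behind them is unknown.

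Rbm10 (ENSMUSG00000031060.9, X:20194629-20228027, mm9) separated the ES groups in every sample. It fell from 32.7 ± 0.683 TPM in WT ES cells (32.5, 33.5 and 32.2) to 4.05 ± 0.366 TPM in the gene trap line (4.27, 3.63 and 4.25; SD, n = 3 each). That is a log2 fold change of -2.74 (SE 0.092, limma adjusted p = 6.7e-05). Its transcript ENSMUST00000084383, at 26.9, 23.8 and 22 TPM in WT, was listed at 0 in all 3 KO samples. There ENSMUST00000141128 held 82.1 ± 2.62% of the gene's TPM, and this transcript was listed at 0 in WT. In md cells the exon 3 clones held 23.2 and 19.7 TPM and the exon 9 clones 7.20 and 3.49 TPM, against 21.4, 23.2 and 23.7 TPM in WT (log2 fold change -1.03, SE 0.56, limma adjusted p = 0.762). A small frameshift deletion need not lower TPM, so these values do not check the labels of KO1 and KO2. Rbm5, a paralog, had 12.2, 9.66, 11.2 and 12.6 TPM in the md clones and 9.62, 9.40 and 9.53 in WT (+0.23, adjusted p = 0.761). In ES cells it had 4.18, 3.24 and 7.83 TPM in KO and 2.75, 3.59 and 2.09 in WT (+0.62, adjusted p = 0.173). Rbm6, another paralog, had log2 fold changes of +0.39 in md (adjusted p = 0.738) and +0.33 in ES cells (adjusted p = 0.123).

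**Figure D1:**
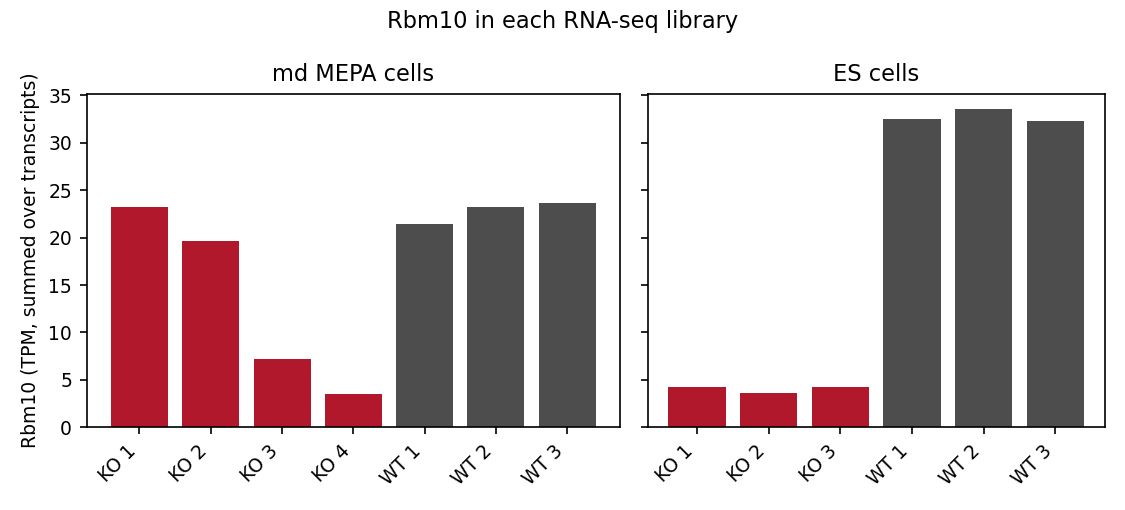
Rbm10 level in TPM (y axis, summed over transcripts) in each of the 13 RNA-seq libraries (x axis), with 1 bar per library, red for KO and grey for WT. In ES cells each gene trap library lies at or below 4.27 TPM and each parental library at or above 32.2 TPM, while the md exon 3 clones (KO 1 and KO 2) lie beside WT and the exon 9 clones (KO 3 and KO 4) below it.

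The first question of the iCLIP data is which RNA regions RBM10 contacts. RBM10 crosslinks lay mostly in introns, at 63.7 ± 6.77% of crosslinks against 46.2 ± 1.99% in IgG libraries (SD, n = 4 each; 2-sided exact permutation p = 0.0286, the smallest that the 70 unpaired splits allow; adjusted p = 0.0327). Exons of noncoding transcripts held 6.66 ± 1.31% against 2.40 ± 0.173%. Coding sequence held less, 5.58 ± 1.69% against 8.83 ± 0.970%, as did intergenic sequence, 10.8 ± 3.06% against 18.5 ± 0.727%. All 3 of these had the same exact permutation p of 0.0286. The 100 nt upstream of 3' splice sites, where the branch point and polypyrimidine tract lie, held 24.5 ± 5.24% of the intronic RBM10 crosslinks and 3.56 ± 0.695% of the IgG ones. These regions make up 1.81% of intronic bases. The 100 nt downstream of 5' splice sites held 9.20 ± 1.72% against 2.67 ± 0.275% and make up 1.66% of intronic bases. The crosslinked nucleotide was C in 37.7 ± 6.70% of RBM10 and 15.4 ± 1.22% of IgG crosslinks, and U in 38.4 ± 4.98% and 54.2 ± 2.05% (exact permutation p = 0.0286 for both). With each RBM10 library kept beside its own IgG library, all 4 pairs shifted the same way in 7 of 8 region classes, in both splice-site regions and for all 4 bases. The exact sign flip p was then 0.125, the smallest that 4 pairs allow, so no share passed in the paired test, which was added after the data were seen.

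**Figure D2:**
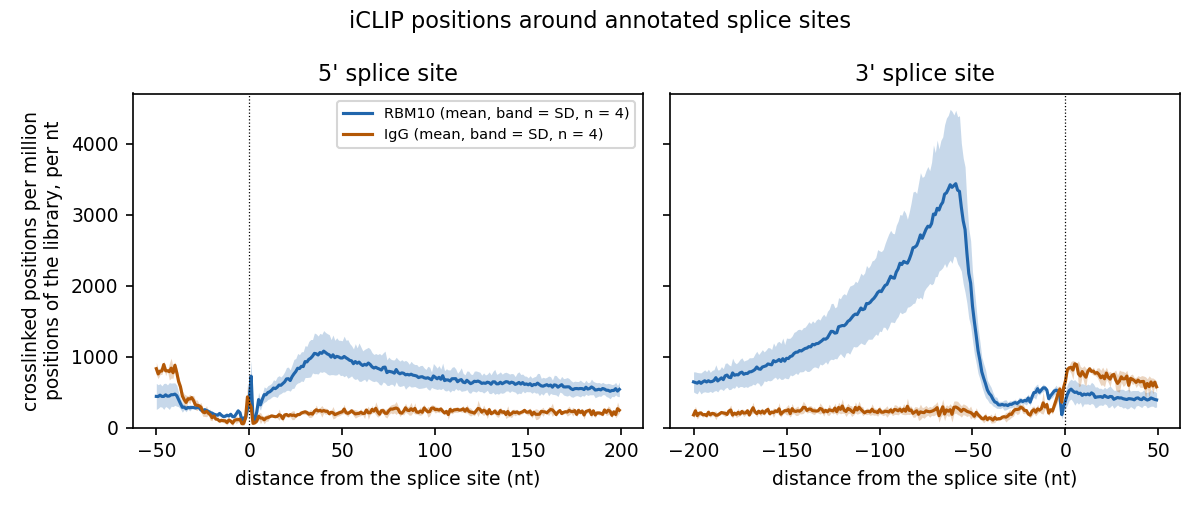
Crosslinked positions at each nt, scaled to the number of positions in the library (y axis), against the distance from annotated 5' and 3' splice sites in nt (x axis), with lines for the means and bands for the SD of 4 RBM10 and 4 IgG libraries. The RBM10 line peaks about 60 nt upstream of the 3' splice site and about 40 nt downstream of the 5' splice site, above the IgG line at both places.

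The libraries also differed in yield and in how often they hit the same nucleotides. RBM10 libraries had a geometric mean of 3.77 times as many crosslinks as IgG libraries and were higher in 4 of 4 pairs. The folds of pairs 1 to 4 were 1.16, 1.29, 27.6 and 4.90, so pair 3 weighs most. The exact permutation p was 0.143 and that of sign flips of the pairs 0.125, the smallest that 4 pairs allow. Between RBM10 libraries 11% of positions were shared, against 1.10% after a shift of 1000 nt. Between IgG libraries 6.05% were shared (1.07% after the shift), and between an RBM10 and an IgG library 4.63% (0.947% after the shift). These shares depend on depth, which was not matched, so they do not rank the groups. In all 4 RBM10 libraries 27660 positions recurred. For shares per chromosome, 0 of 22 differed after adjustment (lowest adjusted exact permutation p = 0.0524), and 12 had an unadjusted p under 0.05. The RBM10 libraries shared 1 sequencing lane and the IgG libraries another, so lane and antibody cannot be told apart in any iCLIP comparison here.

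Of 22772 windows of 5000 nt per strand, 10167 differed between RBM10 and IgG, 6565 higher and 3602 lower in RBM10 (edgeR quasi-likelihood test). U2 is the spliceosomal RNA that pairs with the branch point. A window with 1 of the 27 U2 snRNA genes that held crosslinks (1:157800001-157805000) had 67.6 ± 13.2 CPM (crosslinks scaled to library size) in RBM10. In IgG it had 0.259 ± 0.518 (log2 fold change +7.30). IgG library 1 held 1 crosslink there and the other IgG libraries 0, so the size of this fold is uncertain. Over all U2 genes the share of crosslinks was 3.63 times that in IgG (exact permutation adjusted p = 0.0524). A window of Gnl2 (4:124730001-124735000), which encodes a nucleolar GTPase, held 119 ± 31.3 against 7.30 ± 5.36 (+3.72, edgeR adjusted p = 4.8e-11), with 85.3% of its RBM10 crosslinks in exons of noncoding transcripts. Windows of Ubp1 (9:113865001-113870000, 99.4% intronic, +3.52), Mtmr2 (9:13600001-13605000, +3.62), Tacc3 (5:34005001-34010000, 98.7% intronic, +3.52) and Pkd2 (5:104905001-104910000, 98.9% intronic, +3.45) were also among the 10 with the lowest p. The other 4 held no gene on their strand, among them 13:20750001-20755000 with 476 ± 487 against 14.1 ± 13.1 (+5.01). Malat1, an abundant nuclear noncoding RNA, held 8521 ± 824 against 3746 ± 216 in its window at 19:5795001-5800000 (+1.14, edgeR adjusted p = 0.0712). It passed with the replicate pair as a block (+1.15, edgeR adjusted p = 0.0166), without TMM factors (0.0290), with DESeq2 (adjusted p = 4.35e-05), with at least 10 crosslinks over all libraries (0.0331) without RBM10 library 3 (0.0420) and with pairs 1 and 2 alone (0.00288). The first window of the mitochondrial genome fell by 1.41 on the log2 scale (edgeR adjusted p = 0.0389). That call ended without RBM10 library 3 (0.0962) or 4 (0.239), or without IgG library 1 (0.154), 2 (0.179), 3 (0.118) or 4 (0.112), and with at least 10 crosslinks over all libraries (0.325).

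The share of window calls that were higher in RBM10 moved with the scaling, the filter and the libraries. The median log2 fold change of all windows was 0.44 with TMM factors, 0.59 without them and 0.55 with DESeq2 size factors. Each window was tested against no change and not against that median. The shift is thus part of the calls and favours those higher in RBM10. Without TMM factors 10636 windows passed, 72.9% of them higher in RBM10, and with DESeq2 8692 passed, 74.0% of them higher, against 64.6% of the 10167. With the replicate pair as a block 6180 windows passed, 4441 higher and 1739 lower. With at least 10 crosslinks over all libraries 8330 were higher and 635 lower (92.9% higher), and without RBM10 library 2 the majority turned, with 5284 higher and 5453 lower (49.2% higher). Without RBM10 library 3 the count was 6729, without IgG library 1 6511 and without IgG library 2 4017. In 8667 windows (38.1%) all RBM10 libraries lay on one side of all IgG libraries, where chance gives 2.86%.

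Over gene bodies, 3384 of 9017 genes differed, 1840 higher and 1544 lower in RBM10 (edgeR). Stat2, a transcription factor of interferon signalling, held 458 ± 73.5 CPM against 79.0 ± 20.1 (+2.13, adjusted p = 0.000107). Fanca, of the Fanconi anaemia repair complex, held 644 ± 119 against 125 ± 28.5 (+2.00). Ddx5, an RNA helicase that acts in splicing, held 744 ± 112 against 175 ± 26.8 (+1.79). Among RNA-binding proteins, Rbm3 held 296 ± 112 against 37.9 ± 11.4 (+2.57), Rbm5 307 ± 71.7 against 82.7 ± 18.1 (+1.49) and Rbm10 itself 189 ± 42.5 against 75.3 ± 21 (+1.19, adjusted p = 0.00295). Of the 11 tested genes reported as splicing targets of RBM10, 2 were higher (Rbm5 and Rbm10) and 2 lower, while without TMM factors 5 were higher and 1 lower. The lower ones were Bcl2l1, an apoptosis regulator (-1.39, adjusted p = 0.00404), and Numb, a Notch inhibitor (-0.62, adjusted p = 0.0376, but 0.223 without TMM factors and 0.0604 with DESeq2). Cell cycle genes were higher in 17 of 35 and lower in 1, and interferon genes higher in 13 of 31 and lower in 3. Mitochondrially encoded genes were lower in 8 of 9 (4 with DESeq2) and histone genes in 5 of 6. The direction of these 4 groups held under either other scaling. The share called higher was 54.4% with TMM factors and 75.9% of 3660 calls without them, where the median of all genes moved from 0.05 to 0.34. Without IgG library 2 the count was 1797. In 3568 genes (39.6%) the groups did not overlap, where chance gives 2.86%.

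U12 is the snRNA of the minor spliceosome that pairs with the branch point of minor introns. It held 1.84 ± 1.95% of all RBM10 crosslinks (0.744, 1.09, 0.778 and 4.77% in libraries 1 to 4) and 0.0660 ± 0.0321% of IgG ones. Its exact permutation p was 0.0286, and 0.0524 after adjustment over 11 small RNA families, of which 0 passed and 6 had an unadjusted p under 0.05. Its gene lies at 15:82980074-82980224, and its window differed by +4.81 (edgeR adjusted p = 8.4e-10). The most crosslinked position of each RBM10 library, 15:82980191 on the plus strand, lies in it. When each position was counted once, that window's log2 fold change was -0.28 (edgeR adjusted p = 0.493), so its excess lies in repeated crosslinks at the same positions. A gene this short offers few positions, so this count cannot tell copies of a molecule from separate contacts. U2 held 0.0669% against 0.0184% and 7SK, a regulator of transcription elongation, 0.204% against 0.374%.

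The md RNA-seq comparison asks which genes change in RBM10's absence in pharyngeal arch cells. Of 12090 genes, 2 passed, both lower in the clones (limma; 829, or 6.86%, had an unadjusted p under 0.05). Eif2s3y (Y:346986-365290), a Y-linked subunit of a translation initiation factor, was listed at 0 in all 4 clones and had 4.94, 3.14 and 3.39 TPM in WT (adjusted p = 0.0112). Gm773 (X:53443004-53466058), a predicted X-linked gene, fell from 5.45 ± 0.575 TPM (n = 3) to 0.218 ± 0.235 TPM (n = 4; log2 fold change -2.42, SE 0.19, adjusted p = 0.0112). Both were named after their values were seen. Without KO1 the count was 4 and without KO3 it was 3, and it was 0 without KO2, KO4, WT1, WT2 or WT3. In 1295 genes (10.7%) the groups did not overlap, where chance gives 5.71%. Contrasted with WT, the exon 3 clones gave 24 genes (4 higher, 20 lower) and the exon 9 clones 76 (31 higher, 45 lower). These contrasts were added after the data were seen. They came from 1 fit of all md samples, which share the estimate of the spread.

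The interferon, splicing factor, histone and p53 lists moved as sets in md cells by camera, and none of the 4 calls held with an estimated correlation. Interferon response genes were higher in the clones in 39 of 40 tested, with a median log2 fold change of +0.37 (adjusted p = 4.84e-08, and adjusted p = 0.647 with an estimated correlation). The clones did not share the shift: the mean log2(TPM + 1) of the list was 5.94, 5.84 and 5.87 in KO1, KO2 and KO4 but 5.10 in KO3, below each WT sample (5.19, 5.29 and 5.32). All md cells were cultured with 100 U/ml murine interferon, per the labels. Ifit3, an antiviral protein, had 8.02 ± 3.65 against 1.81 ± 0.338 TPM (+1.56), H2-D1, a class I antigen presenting molecule, 2090 ± 443 against 1274 ± 59.9 (+0.69) and Ifit1 4.40 ± 2.40 against 1.04 ± 0.173 (+1.29). Of the 40, 0 passed over all genes and 0 adjusted over the list alone (limma), and 9 had an unadjusted p under 0.05. Splicing factors lay lower, with 7 of 39 above 0 and a median of -0.15 (adjusted p = 0.00275, and adjusted p = 0.748 with an estimated correlation). Hnrnpa2b1 had 572 ± 88.8 against 779 ± 17.9 TPM (-0.46) and Hnrnpa3 192 ± 27.0 against 244 ± 9.23 (-0.35), both hnRNP proteins that bind pre-mRNA. The call was lost without KO1 (0.0899) or KO4 (0.0944). All 6 histone genes, whose transcripts largely lack the poly(A) tail that these libraries selected, lay higher, median +0.44 (adjusted p = 0.00666, and adjusted p = 0.319 with an estimated correlation), and Hist1h2bc rose adjusted over the list alone (28.8 ± 6.27 against 12.6 ± 1.22 TPM, +1.11). This call was lost without KO3 (0.0972) or KO4 (0.0944). Of 26 p53 targets 17 lay higher, median +0.11 (adjusted p = 0.0380, and adjusted p = 0.319 with an estimated correlation). The cell cycle inhibitor Cdkn1a (19.1 ± 5.2 against 9.16 ± 0.686 TPM, +0.95) and the death receptor Fas (7.19 ± 1.5 against 3.91 ± 0.241, +0.72) rose adjusted over the list alone. This call was lost without KO3 (0.190), KO4 (0.156) or WT2 (0.0909), and with quantile normalization (0.0974) or gene TPM of at least 5 (0.136).

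For the other lists in md cells camera gave no adjusted p under 0.05. The adjusted p was 0.0817 for apoptosis, 0.101 for the cell cycle (just under 0.05 with no filter on low values), 0.108 for leukocyte markers, 0.117 for mitochondrially encoded genes (0.0434 without KO1 and 0.0220 without WT3), 0.313 for palate development, 0.498 for epithelial markers and 0.503 for RBM10 and related RNA-binding proteins. It was 0.748 for fibroblast markers, 0.766 for pharyngeal arch patterning, 0.785 for genes beside Rbm10 (0.987 with Rbm10 itself left out, a test added after the data were seen) and 0.941 for the Notch pathway. It was 0.987 for reported targets, bone, matrix, pluripotency, stress, imprinted and endothelial genes, and 0.988 for germ layers. Adjusted over the list alone, the cell cycle list had 1 member higher and 1 lower, and the reported targets 1 higher. In the bone (+0.08), matrix (+0.03), germ layer (+0.15) and imprinted (+0.02) lists the median and the direction of the test differed in sign, as in the reported targets (-0.00) and stress genes (-0.01). The 2-cell-like, sex chromosome, muscle and neural lists had at most 2 tested members, too few for a set test, and Eif2s3y was the only one of these to pass.

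Exon inclusion in md cells was compared as percent spliced in (PSI). Of 4150 cassette exons 0 passed (limma; 360, or 8.67%, had an unadjusted p under 0.05), and on the logit scale 4 did. Without KO2 the count was 1. Of 5105 other splice events 5 passed (406 at an unadjusted p under 0.05). An alternative 3' site of Glyr1 (16:5021541, set against 16:5021523), a chromatin protein that binds nucleosomes, rose from 42.4 ± 0.979% to 59.3 ± 1.69% (n = 3 and 4; +16.9 points, limma adjusted p = 0.0242). One of Zfp707, a zinc finger gene, fell from 70.1 ± 1.75% to 51.0 ± 2.26% (-19.1 points, limma adjusted p = 0.0242). Mutually exclusive exons rose in Ext2, a heparan sulfate polymerase (8.87 ± 3.93% to 35.5 ± 5.54%, +26.7 points), Epb4.1l3, a membrane skeleton protein (47.7 ± 5.50% to 71.3 ± 3.59%, +23.6), and Chchd3, a mitochondrial inner membrane protein (26.2 ± 15.4% to 88.2 ± 13.8%, +61.9). This count was 1 without KO1 or WT2 and 0 without KO2, KO3, KO4, WT1 or WT3. Of 18725 transcript shares 0 passed (limma; 1461 at an unadjusted p under 0.05), with 3 on the logit scale and 3 without KO2.

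Between the exon 9 and exon 3 clones 451 genes differed, 170 higher and 281 lower in the exon 9 clones (limma, n = 2 each, with WT sharing the estimate of the spread). With 2 clones per deleted exon, clone and deletion cannot be told apart. The median absolute log2 difference was 0.251 to 0.380 between clones and 0.0742 to 0.101 between WT samples. The shared spread may thus understate that of clones. Cd34, a surface sialomucin of progenitor cells, had 0.151 and 0.628 TPM in the exon 3 clones and 234 and 190 in the exon 9 clones, with a WT mean of 43.9 (+7.27, adjusted p = 8.8e-05). Serpinf1, a secreted antiangiogenic factor, had 8.62 and 3.84 against 387 and 557, WT mean 58.8 (+6.09, adjusted p = 0.00100). Bgn, a matrix proteoglycan, had 2.75 and 3.29 against 318 and 227, WT mean 73.8 (+6.07). Msln, a mesothelial surface protein, had 48.3 and 53.5 against 2.13 and 3.39, WT mean 36.9 (-3.81). Hs6st2, a heparan sulfate modifying enzyme, had 22.5 and 17.6 TPM in the exon 3 clones and was listed at 0 in both exon 9 clones. The WT mean lay between the pairs of clones in 420 of the 451 genes. Choosing genes by the difference between the pairs favours this, so the count shows nothing on direction against WT. Of the matrix list 5 of 28 were higher and 3 lower, of the fibroblast markers 3 of 13 were higher and 1 lower, and of the interferon list 7 of 40 were lower in the exon 9 clones. The mean log2(TPM + 1) of the interferon list was 5.10 in KO3 alone, while KO4, the other exon 9 clone, had 5.87, level with the exon 3 clones (5.94 and 5.84). Without KO1 284 genes passed, without KO3 1168 and without KO4 2228.

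In ES cells 1576 of 12860 genes passed, 968 higher and 608 lower in the gene trap line (limma). Of these, 267 differed at least 2-fold, 110 higher and 157 lower. Mest (6:30673547-30698457), an imprinted hydrolase, rose from 2.15, 2.06 and 2.90 TPM to 61.5, 68.5 and 57.6 (+4.24, adjusted p = 6.7e-05), and Igf2, an imprinted growth factor, from 6.64 ± 1.75 to 26.4 ± 1.35 (+1.87, adjusted p = 0.00533; SD, n = 3). Myl9, a smooth muscle myosin chain (+2.66, with 29.0 TPM in WT3 against 4.88 and 4.66 in the other WT samples), Car4, a carbonic anhydrase (+2.03), Wt1, a transcription factor of kidney and gonad (+1.99), and Hspa1a, a heat shock chaperone (+1.93), also rose. So did Sall2 (+1.89), Pou3f1 (+1.88) and Lef1 (+1.88), which are developmental transcription factors. Nupr1, a stress-induced chromatin protein, had 14.2, 1.31 and 2.36 TPM in KO and 128, 148 and 38.9 in WT (-4.22, SE 0.78, adjusted p = 0.0269). Atf4, the transcription factor of the integrated stress response, had 63.9, 18.7 and 17.2 against 175, 178 and 139 (-2.53, SE 0.46, adjusted p = 0.0269). Its targets Chac1 (-2.99) and Trib3 (-2.70) fell too, as did G0s2 (-2.26), Jdp2 (-2.05), Gdf15 (-2.03) and the small RNA SCARNA16 (-2.09). AC164075.1 (7:87297706-87297765), annotated as a microRNA gene, was listed at 0 in KO and had 18, 14.4 and 20.9 TPM in WT. The naming rule left out microRNAs by symbol only, and this gene carries a clone name.

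**Figure D3:**
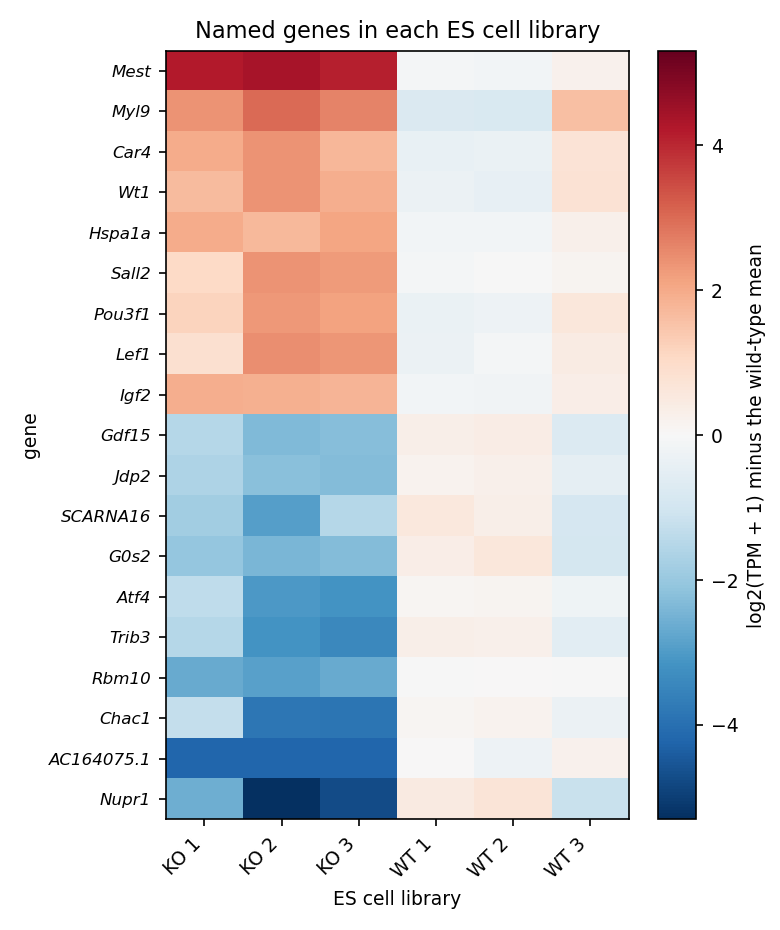
Heat map of log2(TPM + 1) minus the WT mean (colour scale) of named ES genes (y axis) in the 3 gene trap (KO) and 3 parental (WT) ES libraries (x axis). The upper 9 genes are higher in all KO libraries and the others lower, and for Nupr1, Atf4, Chac1 and Trib3 KO 1 and WT 3 are the libraries of their groups nearest the other group.

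The ES samples differed within groups. On the first principal component (54.0% of the variance) KO1 (-5.02) and WT3 (16.4) lay nearest the other group, with KO2 and KO3 at -36.3 and -28.8 and WT1 and WT2 at 26.6 and 27.2. The gene count was 3985 without KO1, 61 without KO2, 49 without KO3, 21 without WT1, 49 without WT2 and 1865 without WT3, and 5716 with KO1 and WT3 both left out, a fit added after the data were seen. Mest, Igf2 and Rbm10 passed under each of the 13 alternatives run for them. Nupr1, Atf4, Chac1, Trib3, Gdf15, Jdp2, SCARNA16, Myl9, Car4, Wt1, Sall2, Pou3f1 and Lef1 did not pass without KO2, KO3, WT1 or WT2, each left out in turn. For Atf4 the limma adjusted p was then 0.103, 0.0976, 0.115 and 0.108, and for Nupr1 0.101, 0.105, 0.115 and 0.108. G0s2 did not pass without KO2 (0.0997) or KO3 (0.0942), nor Chac1 without WT3 (0.0550). With no filter on low values Myl9 (0.0670), Lef1 (0.0658), Chac1 (0.0618) and SCARNA16 (0.0633) did not pass, nor SCARNA16 with a pseudocount of 0.1 (0.0519). The share of calls that were higher was 61.4%, against 42.5% of 1553 (660 higher, 893 lower) with median-ratio scaling and 46.2% of 1557 (719 higher, 838 lower) with quantile normalization. In 4929 genes (38.3%) the groups did not overlap, where chance gives 10%. The comparison is of 1 gene trap line with its parental line, so line and genotype cannot be told apart.

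Of 30 pluripotency genes in the gene trap line 10 fell, 3 rose and 17 did not pass (14 fell and 6 rose adjusted over the list alone; 12 fell and 1 rose with median-ratio scaling, 12 and 2 with quantile normalization), with camera adjusted p = 0.0642 (0.480 with an estimated correlation, 0.0128 with no filter on low values, 0.0357 with gene TPM of at least 5, 0.0370 with quantile normalization, 0.0291 without KO2, 0.0366 without KO3 and 0.0478 without WT2). The orphan receptor Nr5a2 (12.0 ± 0.471 against 19 ± 0.598 TPM, -0.62) and the transcription factors Tcfcp2l1 (-1.67), Tbx3 (7.58 ± 3.20 against 27.6 ± 1.70, -1.81) and Prdm14 (-0.66) had the lowest p. Named after their values were seen, Nanog (189 ± 35.1 against 331 ± 16.2, -0.82), Esrrb (104 ± 29.4 against 232 ± 25.6, -1.19) and Klf2 (117 ± 31.3 against 250 ± 31.9, -1.11), factors of the naive state, also fell, while Utf1 (590 ± 119 against 345 ± 37.8, +0.76), Socs3 (+0.82) and Sall4 (+0.50) rose. Of 23 genes of the germ layers and exit from pluripotency 7 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.162, and 0.00529 with no filter on low values). The neural factor Sox3 (+1.42) and the endoderm adaptor Dab2 (+0.85) rose, and Lefty2, a Nodal inhibitor (23.7 ± 0.900 against 58.2 ± 4.59, -1.26), and Cdx1 (-0.86) fell. Otx2 (51.5 ± 15.7 against 22.1 ± 2.17, +1.14) and the DNA methyltransferase Dnmt3a (159 ± 25.6 against 68.4 ± 25.9, +1.25), both of the primed state, rose as well. Of 19 imprinted genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera 0.0642, but 0.0418 with no filter on low values and 0.0478 without WT2), with Dlk1, a Notch-like inhibitor of differentiation (6.07 ± 0.883 against 1.5 ± 0.411, +1.51), and Nespas (+0.54) beside Mest and Igf2.

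The list of genes beside Rbm10 on the X chromosome, which as fixed holds Rbm10 itself, was lower as a set, with 5 of 15 fallen and 0 risen (6 fallen and 1 risen adjusted over the list alone), a median of -0.29 and camera adjusted p = 0.00197 (adjusted p = 0.480 with an estimated correlation), the one ES list to pass. The knockout itself sets part of that value. With Rbm10 left out of the list, a test added after the data were seen, 4 of 14 neighbours had fallen, the median was -0.257 and the camera adjusted p was 0.0255 (0.547 with an estimated correlation and 0.0664 without WT3). The 4 were the protease inhibitor Timp1 (20.6 ± 5.12 against 42.1 ± 1.91 TPM, -1.02, limma adjusted p = 0.0212), the respiratory chain subunit Ndufb11 (85.3 ± 8.54 against 135 ± 10.5, -0.66, 0.0223), the kinase Araf (-0.55, 0.0232) and the kinase Cdk16 (-0.32, 0.0427). Ndufb11 overlaps Rbm10, so reads of the 2 genes could be shared. Of 27 stress genes 8 rose and 6 fell (8 and 9 adjusted over the list alone; 6 and 7 under either other scaling; camera 0.908). The heat shock genes Hspa1a and Hspa1b (+1.80) and the immediate early genes Jun (+0.85) and Junb (+0.72) rose, as did Hspa5, an endoplasmic reticulum chaperone (186 ± 80.9 against 54.3 ± 6.77, +1.65), while Herpud1, of the same compartment, fell (7.24 ± 4.19 against 23.8 ± 1.98, -1.70).

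RBM10 and related RNA-binding proteins had 4 of 21 risen and 1 fallen, Rbm10 itself (6 and 1 adjusted over the list alone; 3 and 1 with median-ratio scaling, 1 and 1 with quantile normalization; camera 0.307). Rbm14, a paraspeckle protein (76.2 ± 23.2 against 33.7 ± 1.22, +1.10), Sf1, which binds the branch point (+0.41), and Rbm17 (+0.42) were those with the lowest p after Rbm10. Splicing factors had 3 of 41 risen, Elavl1 (+0.53), Hnrnpd (+0.43) and Srsf10 (+0.38), and 0 fallen (0 and 0 adjusted over the list alone; 1 and 1 under either other scaling; camera 0.0642, but 0.00619 with no filter on low values, 0.00897 without KO1 and 0.0403 without KO2). Interferon genes had 4 of 19 risen and 3 fallen (8 and 3; 0.594), with the RNA sensor Ddx58 down (-0.72) and Psmb8 (+1.03) and Irf1 (+0.99) up. Cell cycle genes had 3 of 33 risen and 2 fallen (3 and 2; 0.908; 2 risen and 3 fallen under either other scaling), with the inhibitor Cdkn2a (+0.73) up and Tyms (-0.55) and Cdkn1a (-0.74) down. Of 17 matrix genes 4 rose and 2 fell (5 and 2; 0.908; 3 and 2 under either other scaling), among them the basement membrane collagen gene Col4a1 (+1.24) and Fbln1 (-1.04). Of 28 p53 targets 1 rose and 3 fell (2 and 3; 0.908), with Ptpn14 up (+1.10) and Sesn2 down (-0.59). Of 10 palate genes 1 rose and 3 fell (3 and 4; 0.686), with Bmpr1a up (+0.48) and Pdgfc down (-0.96). Of 4 sex chromosome genes 3 fell and 0 rose (3 and 0; 2 fallen with quantile normalization; camera 0.0642, but 0.00619 with no filter on low values, 0.0469 without KO2 and 0.0478 without WT2): Uty (-0.63), Ddx3y (-0.55) and Tsix (-0.52).

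In these brackets the first 2 counts are adjusted over the list alone, risen then fallen, and the last value is the camera adjusted p. Pharyngeal arch genes had 2 of 6 risen, among them Hand1, and 0 fallen (3 and 1; 0.622, but 0.00884 with no filter on low values), bone genes 1 of 4 fallen, Spp1 (0 and 2; 0.188), and Notch genes 1 of 26 risen, Dll3, and 1 fallen, Notch4 (1 and 1; 0.947). Apoptosis genes had 2 of 30 risen, Bok and Bcl2l11, and 2 fallen, Casp6 and Casp9 (2 and 2; 0.908). Reported RBM10 targets had 1 of 10 fallen, Rbm10 (1 and 1; 0.947). Epithelial markers had 2 of 14 risen, Cldn6 and Cldn7 (2 and 1; 0.117, but 0.0329 with no filter on low values), endothelial markers 1 of 10, Sox18 (1 and 2; 0.908), and leukocyte markers 2 of 5 fallen, Laptm5 and Cd68 (0 and 3; 0.0642). Muscle markers had 1 of 5 risen, Actc1, and 1 fallen, Mylpf (84.4 ± 28.3 against 236 ± 41.2 TPM, -1.51; 2 and 1; 0.947), and fibroblast markers 1 of 6 risen, Acta2, and 1 fallen, Fbln1 (1 and 1; 0.908). By limma 0 passed of 9 genes of the 2-cell-like state (0 at an unadjusted p under 0.05; camera 0.908), of 11 neural markers (2 unadjusted; 0.908) and of 6 histone genes (0 unadjusted; 0.947). The same held for 14 mitochondrially encoded genes (3 unadjusted), which all lay above 0 with a median of +0.42 (camera adjusted p = 0.0935, and adjusted p = 0.973 with an estimated correlation; 0.0418 with no filter on low values and 0.00492 without KO1). With median-ratio scaling epithelial markers had 1 risen and 1 fallen, endothelial markers 1 and 2, bone genes 0 and 2, Notch genes 1 and 2, leukocyte markers 0 and 3 and neural markers 0 and 1. With quantile normalization these were 1 and 0, 1 and 1, 0 and 2, 1 and 2, 0 and 2, and 0 and 1, and 1 mitochondrially encoded gene rose. The median and the direction of the test differed in sign for the matrix (-0.03), endothelial (+0.09), 2-cell-like (+0.00), reported target (+0.04), neural (+0.04) and histone (+0.06) lists.

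Cassette exons changed in 8 of 3757 in ES cells, 4 higher and 4 lower in the gene trap line (limma; 560, or 14.9%, at an unadjusted p under 0.05). An exon of Tubd1, delta tubulin of the centriole (11:86370197-86370289), rose from 10.4 ± 2.09% to 80.2 ± 6.23% inclusion (SD, n = 3; +69.9 points, SE 3.64, adjusted p = 0.0036). Exons of Sbf2, a regulator of endosomal trafficking (7:117484804-117484878, 31.6 ± 7.32% to 77.8 ± 1.26%), Ext2 (2:93660187-93660306, 16.3 ± 3.85% to 51.0 ± 1.33%) and Rbm26, an RNA-binding protein (14:105538308-105538379, 46.2 ± 3.71% to 80.7 ± 1.5%), also rose. Exons of Ap1s3, an adaptor of vesicle coats (1:79620257-79620365, 100% to 54.1 ± 9.61%), Fam69a (5:108353604-108353738, 99.5 ± 0.854% to 68.4 ± 6.0%), the sterol enzyme gene Sc4mol (8:67208391-67208432, 30.1 ± 4.06% to 1.82 ± 3.15%) and the histone deubiquitinase gene Usp49 (17:47811665-47811869, 97.0 ± 2.83% to 70.4 ± 2.25%) fell. With events of at least 5 TPM 33 exons passed, 29 higher and 4 lower, and on the logit scale 25. The count was 15 without KO1, 1 without KO2, 1 without KO3, 2 without WT1, 0 without WT2 and 0 without WT3, and 0 with KO1 and WT3 both left out.

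**Figure D4:**
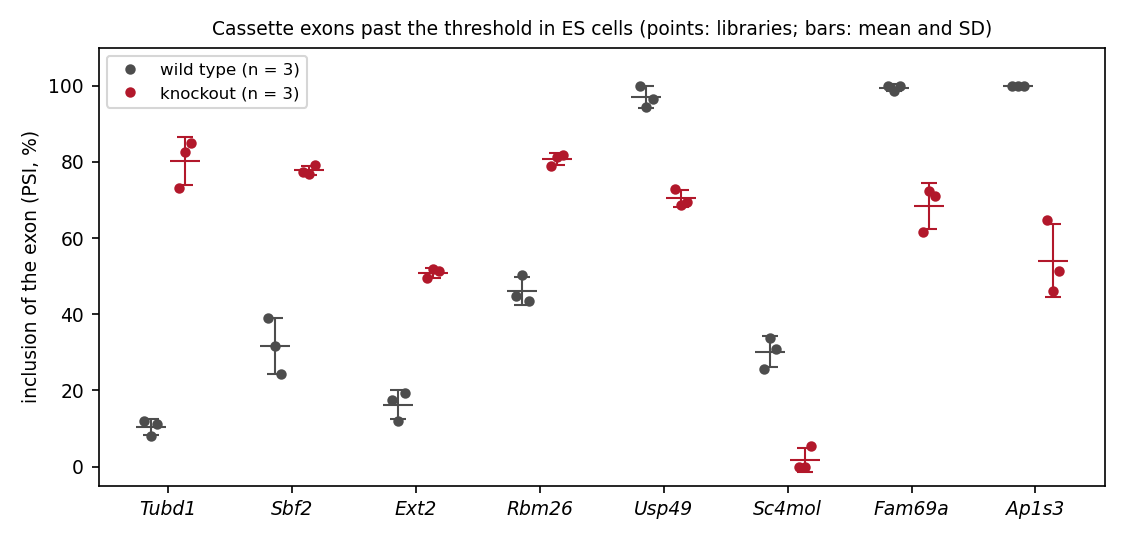
Inclusion in percent (y axis) of the 8 called cassette exons (x axis) in the 3 gene trap and 3 parental ES libraries, with a point per library and bars for the mean and SD. The groups do not overlap for any of the 8, and Tubd1 shows the widest gap between means, from 10.4 to 80.2%.

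Of 4694 other splice events in ES cells 8 passed, 5 higher and 3 lower (limma; 559 at an unadjusted p under 0.05). An alternative 5' site of Wnk1, a kinase of ion transport, fell from 44.2 ± 4.46% to 10.6 ± 1.18% (-33.6 points, limma adjusted p = 0.0217), and an alternative 3' site of Cpsf4, a polyadenylation factor, rose from 13.3 ± 3.11% to 51.8 ± 5.96% (+38.5, limma adjusted p = 0.0382). An alternative 5' site within Rbm10 itself (X:20222723, set against X:20222720) fell from 98.0 ± 0.917% to 6.15 ± 3.35%. In the gene trap line Rbm10 held 4.05 TPM, mostly as ENSMUST00000141128, which was listed at 0 in WT. This event cannot be told apart from the effect of the gene trap on its own gene. Of 18872 transcript shares 8 passed (2315 at an unadjusted p under 0.05), among them transcripts of Rbm10, Tubd1, Masp2 (+31.1 points), Rbm26 (+30.2) and Usp49 (-28.8). The limit given for the Rbm10 event applies to the Rbm10 transcripts too. The event count was 17 without KO1, 5 without KO2, 3 without KO3, 5 without WT1 and 3 without WT2. The share count was 26 without KO1, 1 without KO2, KO3 or WT2, 2 without WT1 and 3 without WT3.

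Whether the change differs between cell types was tested in 10558 genes, of which 104 passed, 53 with a higher log2 fold change in md cells and 51 with a lower one (limma; 2273 at an unadjusted p under 0.05). Nupr1 had +0.55 in md and -4.22 in ES cells (difference +4.77, adjusted p = 0.0484), and Jdp2, a repressor of AP-1, a difference of +2.23 (adjusted p = 0.0363). Dnmt3a had -0.25 and +1.25 (difference -1.50, adjusted p = 0.0379), and Eif2s3y a difference of -2.31 (adjusted p = 0.000493). Across genes, which are not independent replicates, the log2 fold changes in the 2 cell types had Pearson r = -0.113 and Spearman rho = -0.159. Of the ES calls tested in md cells, 461 of 1176 (39.2%) had the same direction there. The count was 1310 without md KO3, 745 without ES KO1, 261 without md KO2 and 196 without ES WT3. It was 6, 7 and 8 without md WT1, WT2 and WT3, 10 and 11 without ES KO2 and KO3, and 8 without ES WT1 or WT2.

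No cassette exon was called in both cell types among 2714 tested in both (0 were called in md cells, so the overlap could only be 0). Of the 7 ES-called exons tested in md cells 5 moved in the same direction (sign test p = 0.453, an exact test). With events of at least 5 TPM, 20 of 23 did (exact sign test p = 0.000488) among 1675 tested in both, again with 0 called in md cells. In md cells the Tubd1 exon differed by +26.2 points (limma adjusted p = 0.214), that of Rbm26 by +8.14 (0.486) and that of Usp49 by -26.4 (0.207). That of Ext2 differed by +26.7 (0.453), though the same exon passed in md cells within its mutually exclusive event (limma adjusted p = 0.0394). The Sbf2 exon differed by +0.483 (limma adjusted p = 0.974). Exons of Ap1s3 (+16.7, limma adjusted p = 0.449, unadjusted p = 0.0226) and Sc4mol (+1.67, adjusted p = 0.867) went against their fall in ES cells. At an unadjusted p under 0.05 in both, 61 exons were found, 52 of them in the same direction, against 18.6 in the same direction for independent lists. Of the 52, 39 were higher and 13 lower in KO. They included exons of Mfge8, a milk fat globule protein (+24.4 points in ES and +21.8 in md cells), Ciz1, a replication factor (+25.4 and +19.9), Agfg2 (+34.0 and +26.8) and the splicing factor Puf60 (+11.2 and +10.3).

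RBM10 crosslinks were then set beside these exons, in the 100 nt upstream and the 100 nt downstream of each. Exons higher in KO in both cell types (39 exons, limma unadjusted p under 0.05) had a mean of 13.7 RBM10 crosslinked positions upstream. Tested exons called neither higher nor lower at a limma unadjusted p under 0.05 had 7.23 (permutation test among exons of like expression, adjusted p = 0.00828). IgG positions there had means of 0.769 against 0.607 (permutation adjusted p = 0.361), too few to show whether the control has a like excess. Downstream the 39 exons had 9.10 RBM10 positions against 4.86 (permutation adjusted p = 0.0440), so the excess was not confined to the upstream side. Upstream, the 205 exons higher in the md clones had 8.49 against 7.0 RBM10 positions (permutation adjusted p = 0.00828). IgG positions there were also more, 0.737 against 0.609 (unadjusted permutation p = 0.0106, adjusted p = 0.158), so this excess cannot be called particular to RBM10. Downstream these exons had 5.60 against 4.83 RBM10 positions (permutation adjusted p = 0.0488). The 301 higher in the ES gene trap line had 7.47 against 6.25 upstream (permutation adjusted p = 0.0846) and 4.69 against 4.14 downstream (0.401). Upstream of exons lower in KO the permutation adjusted p was 0.457 in md, 0.568 in ES cells and 0.568 in both. Rbm26 had 39 RBM10 positions upstream, Mfge8 32, Ciz1 21, Puf60 16 and Agfg2 9, while Tubd1 had 1 and Usp49 0. The iCLIP was done in md cells only, so the ES exons were compared with contacts measured in another cell type.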

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

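The tests of explanations in this part, of other splits of the samples, of the Y-linked genes, of the genes beside Rbm10 and of the exons shared by both cell types, were all chosen or specified only after the results were seen.

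Of 4 Y-linked genes 2 were absent from the TPM of all md clones. Eif2s3y and Ddx3y were listed at 0 in all 4 clones, with 1.30, 0.898 and 1.46 TPM of Ddx3y in WT, Uty was listed at 0 in KO1, KO3 and KO4 and had 0.266 TPM in KO2 (WT 0.951, 0.925 and 0.627), and Kdm5d had 0.486, 0.141, 0.330 and 0.307 TPM (WT 0.583, 0.573 and 0.499). Reads shared with the X-linked copy Eif2s3x would leave at least 1.88 TPM of Eif2s3y in each clone at the lowest WT ratio, where 0 was listed. Male ES cells mixed into the WT libraries would bring about 265 TPM of the ES marker Dppa5a, whose highest WT value was 1.17 TPM. Loss of the Y chromosome, or clones grown from cells without it, may apply but stays open, since 2 of the Y-linked genes of at least 0.5 TPM in WT, and not all of them, were listed at 0 in all clones, and Kdm5d was not.

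Genes beside Rbm10 were lower in the ES gene trap line, with a median of -0.257 over 14 tested neighbours and 11 of them below 0. Of 12554 runs of as many consecutive genes 1.47% had a median as low, which argues against a chance run. The other 484 X-linked genes had a median of -0.0095 (interval -0.053 to 0.037), which argues against a shift of the whole chromosome. In md cells the neighbours were not lower, with a median of -0.0163 and 39.4% of runs as low, which goes against loss of RBM10 itself lowering its neighbours. TPM do not show that the md clones lack RBM10 function, which keeps that explanation open, so it cannot be told apart from an effect of the inserted cassette. A local effect of the gene trap may be the source, as a hypothesis found and tested on the same data.

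Cassette exons moved the same way in md and ES cells more often than independent lists would, 52 against 18.6. Over 700 combinations of splits of the md and the ES samples the real count was met by 2, the real one included, with a highest other count of 52 and a median of 3 (exact permutation p = 0.00286). Other groupings of the samples thus rarely reached this count. Regrouping changes how many exons pass in each cell type as well as whether they agree. The permutation test therefore cannot tell agreement in direction from a signal within each comparison. Exons higher in both had more RBM10 crosslinked positions than exons of like expression, upstream (permutation adjusted p = 0.00828) and downstream (0.0440). This goes with RBM10 bound beside the exons and repressing inclusion, but does not single out the upstream side. IgG positions upstream (permutation adjusted p = 0.361) were too few to exclude a like excess in the control. The Tubd1 exon had 1 RBM10 position upstream and that of Usp49 0, so indirect effects stay open.

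Single libraries stood apart from the other 3 of their group in 8 of 105 groups of values (7.62%), where chance gives about 1 in 20. The mean log2(TPM + 1) of the interferon list was 5.10 in md KO3 and 5.94, 5.84 and 5.87 in the other clones, with 5.19, 5.29 and 5.32 in WT. RBM10 library 4 had 2.24% of its crosslinks at its highest position (others 0.238, 0.437 and 0.303%), 0.0346% in U1, 4.77% in U12 (0.744, 1.09 and 0.778%) and 9.77% on chromosome 15, where U12 lies (5.98, 6.17 and 6.31%). RBM10 library 3 had 3.48% on chromosome 16 (3.12, 3.10 and 3.12%) and 2.62% on the X chromosome (2.36% at most in the others). IgG library 4 had 4.24% on chromosome 1 (4.66, 4.70 and 4.72%).

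The change differed between md and ES cells in 104 genes by limma. Among those named, the difference of log2 fold changes was 4.77 for Nupr1, 2.23 for Jdp2, 2.16 for Pltp, 2.07 for Mras and 2.04 for Aff1, all higher in md cells, and -1.47 for Prps2, -1.50 for Cyr61, -1.50 for Dnmt3a, -2.19 for Ap1s3 and -2.31 for Eif2s3y. Of 100 regroupings, the real one included, 3 gave as many genes, and the highest other gave 554, several times the real count, which points to a structure of the samples whose source was not tested.

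Other splits of the same samples were set beside the other counts. For md genes 3 of 35 splits gave as many as the real 2 (highest other 2), so chance was not excluded. For md cassette exons and transcript shares the real count was 0, which each split reaches, so the splits test nothing there (highest others 2 and 4). For md other splice events 1 of 35, the real split with 5, gave as many (highest other 2). For iCLIP windows 1 of 35 gave as many as 10167 (highest other 6) and for iCLIP genes 1 of 35 as many as 3384 (highest other 0). Among the 8 iCLIP splits that part all 4 pairs, the highest other count was 0 for genes. The 10 splits of the ES samples are too few for a share under 0.05. The real counts, each reached in 1 split, were 1576 genes (highest other 5), 8 cassette exons (0), 8 other splice events (1) and 8 transcript shares (0).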

How the results depend on the processing

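The contrasts of exon 3 or exon 9 clones with WT and the fit without ES KO1 and WT3 together were chosen after the data were seen. So were the test of the list of genes beside Rbm10 without Rbm10 and the fits of iCLIP pairs 1 and 2 alone. The same holds for the paired test of iCLIP shares and the alternatives of iCLIP genes. Where a value moved, the cause was not tested, except that fewer samples or genes were used where a library was left out or a filter was stricter. The md genes (2) were 0 with a pseudocount of 0.1, 6 with no filter on low values, 0 with gene TPM of at least 5, 1 with arrayWeights and 0 to 4 without a library. The contrasts of the exon 3 and exon 9 clones with WT, in 1 fit of all md samples, gave 24 and 76. The md cassette exons (0) were 4 on the logit of PSI and 0 to 1 without a library. The md transcript shares (0) were 2 with gene TPM of at least 5, 3 on the logit and 0 to 3 without a library, and the md other splice events (5) 0 to 1 without a library. The ES genes (1576) were 774 with no filter on low values, 7246 with arrayWeights, 5716 without KO1 and WT3 (1426 shared) and 21 to 3985 without a library. The ES cassette exons (8) were 33 with event TPM of at least 5, 5 with at least 0.1, 25 on the logit, 0 without KO1 and WT3 and 0 to 15 without a library. The ES transcript shares (8) were 14 with gene TPM of at least 5, 49 on the logit and 1 to 26 without a library, and the ES other splice events (8) 13 with event TPM of at least 5 and 3 to 17 without a library. The clone contrast (451) gave 284 to 2228, and the difference between cell types (104) 6 to 1310, without a library. The overlap of cassette exons could only be 0, as 0 were called in md cells in each setting.

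The set tests passed for 4 lists in md cells, 2 with gene TPM of at least 5, 0 with an estimated correlation and 1 to 5 without a library. In ES cells 1 list passed, 9 with no filter on low values, 2 with gene TPM of at least 5, 2 with quantile normalization, 0 with an estimated correlation and 1 to 4 without a library. The iCLIP windows (10167) were 5154 with windows of 1000 nt and 4017 to 11695 without a library. The U12 window (15:82980001-82985000) went from +4.81 to -0.28 when each position was counted once. The iCLIP genes (3384) ranged from 1797 to 3848 without a library. The log10 difference of the library totals (0.576) ranged from 0.368 to 0.813 without a library. With tests that passed or failed in both fits counted alike, the outcome for named windows was the same under 198 alternatives, while 12 calls were gained, 7 lost and 1 reversed. For gene lists it was the same under 676, with 23 gained and 17 lost, and for named genes and exons under 287, with 117 lost. Depth limits the IgG libraries 3 and 4 most, with 103017 and 157986 crosslinks.

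With a replicate block the counts were 0 for md genes, 0 for md other splice events, 422 for ES genes (Myl9 at 0.0517 and SCARNA16 at 0.0615 did not pass), 0 for ES cassette exons, 0 for ES transcript shares, 2 for ES other splice events, 2 lists in md cells (interferon, and epithelial markers at 0.0342, while splicing factors had 0.0888, histone genes 0.0888 and p53 targets 0.123) and 6180 iCLIP windows. In RNA-seq the samples share only a number. Same-numbered samples had correlations of deviations of -0.110, -0.0012 and -0.0606 in md and 0.165, -0.135 and 0.0388 in ES cells, and not every sample correlated best with its own number. For iCLIP, where the numbers pair the libraries, the intron share of 63.7% had an exact sign flip p of 0.125, and the block changed no other count by over 1.5 times (iCLIP genes 2627).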

Other observations

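The gene lists, the naming rule, the clone contrast and the window fits not marked as added were chosen before the data were examined. The other values in this part come from tables made after the main results were seen.

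RBM10 crosslinks over other gene groups went both ways. In the list of genes beside Rbm10 on the X chromosome 6 of 12 were higher in RBM10 than in IgG libraries and 0 lower. Of 19 RBM10 and related RNA-binding proteins 9 were higher and 2 lower, among the higher ones Rbm17 (+1.69) and U2af2 (+1.26). Both lists hold Rbm10 itself, which is counted among the higher genes of each. Splicing factors had 12 of 39 higher and 9 lower. Of developmental groups, 0 of 12 palate genes were higher and 5 lower, 0 of 7 bone genes higher and 4 lower, and 0 of 10 pharyngeal arch genes higher and 3 lower. Without TMM factors splicing factors had 18 higher and 3 lower, and with each position counted once 8 higher and 13 lower, so their direction depends on the scaling and counting. Without TMM factors 1 palate gene was higher and 4 lower, and 2 bone and 2 pharyngeal arch genes were lower. Lars2, a mitochondrial leucyl-tRNA synthetase, had 123 ± 34.6 CPM in RBM10 and 469 ± 151 in IgG libraries (-2.20, edgeR), and Npas3 differed by -1.41.

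The Y-linked Eif2s3y stood at 3.51, 2.30 and 2.47% of its X-linked copy Eif2s3x in the 3 WT md samples and at 28.5, 31.5 and 24.7% in WT ES samples. Eif2s3x itself had 99.9, 122, 132 and 81.9 TPM in the md clones and 141, 136 and 137 in WT. In the ES gene trap line Eif2s3y had 41.8, 36.3 and 32.6 TPM against 34.4, 37.6 and 34.0.

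Further genes differed between the exon 3 and exon 9 clones, where clone and deleted exon cannot be told apart. Tmem45a was listed at 0 in both exon 3 clones and had 17.1 and 35.6 TPM in the exon 9 clones, and Armcx3 was listed at 0 against 21.1 and 18.8, with a WT mean of 3.4. Ptprf, a receptor phosphatase, had 15.4 and 30.7 TPM in the exon 3 clones and was listed at 0 in the exon 9 clones, with a WT mean of 20.5. Of the 451 genes that differed between the pairs, 9 were past the threshold against WT in both pairs in opposite directions and 0 in the same direction. The choice of genes by that difference favours opposite directions, so these counts do not show that the deletions act in opposite ways.

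The most crosslinked position of IgG libraries 3 and 4, at 10:23039705, took 3.24 and 12.1% of their crosslinks and lies in no gene on its strand. That of IgG libraries 1 and 2 was 17:39985127, in a window that held many crosslinks in both groups (17:39985001-39990000, -0.78, edgeR adjusted p = 0.251). That window passed with pairs 1 and 2 alone (-0.68, edgeR adjusted p = 0.0430, a fit added after the data were seen) and with each position counted once (-1.98, edgeR adjusted p = 3.95e-06). The window beside it, 17:39980001-39985000, also among those with the highest counts, did not pass in the main fit (-1.12, edgeR adjusted p = 0.157).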
